A study of Mus musculus with 60 samples.

How the data were processed

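RNA from the hippocampus of mice was sequenced in 60 samples, which the labels divide by genotype, age and sex into 12 groups of 5. The genotypes are wild type (WT) and NLGF, an App knock-in line that carries mutations of familial Alzheimer's disease in the mouse App gene. The ages are 3, 8 and 24 weeks. Libraries were made from total RNA after depletion of ribosomal RNA, per the labels' protocols. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part.

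The authors deposited a table of raw counts per gene symbol with 1 column per sample. FastQC, STAR, edgeR, DESeq2 and the build mm10 are named in the submitters' processing notes without versions, and the read counter, the annotation and the strand setting are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene can therefore not be told apart in the deposited counts. A second table holds the genes the authors called between the genotypes at each age. Per the file headers, it gives the mean of normalized counts, the log2 fold change of NLGF over WT with its standard error, and the unadjusted and adjusted p-value of the authors' test. The count table holds 35976 gene symbols, of which 4405 have a count of 0 in every sample, and 32501 symbols (90.3%) match a RefSeq symbol. Coordinates are those of mm10 in the GENCODE vM21 annotation.

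Every count and level below was computed from the deposited counts in R 4.3.3. Each comparison was fitted with edgeR 4.0.16: genes were filtered with filterByExpr on the groups compared (minimum count 10), scaled with TMM, and tested with the robust quasi-likelihood F-test, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. Levels are CPM, counts scaled to the TMM-adjusted library total, given as mean ± SD.

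The genotypes were compared at each age among its 20 samples, with sex as a covariate. The difference of the genotype effect between ages was fitted on all 60 samples with sex within age. The genotype effect of males minus that of females was tested at each age. Change with age was fitted on the 30 WT samples with sex as a covariate. In addition, 34 gene lists with 714 members, 710 of them in the count table, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Lists with fewer than 5 measured members would not have been tested. The comparisons, the lists, the alternatives and the rule for naming genes were written before the data were examined, except where a setting is said to have been chosen later.

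The genes named are App in every comparison, any gene called at all 3 ages, up to 10 higher and 10 lower called genes with the largest fold change among those with a mean of at least 1 CPM and the same direction in both sexes (unnamed gene models left out), the 3 with the smallest p-value, up to 4 called members of each list (3 for age), and for differences between ages the 5 higher and 5 lower with the smallest p-value. A few further genes are named as chosen after their values were seen. Some genes that the rule would name are not reported here.

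The fits were tested on simulated data with the real means and library sizes. For the genotype comparison at week 8, run on 16354 genes, 96% of genes changed 2-fold and 30% of those changed 1.25-fold were recovered. For week 24, run on 16393 genes, the shares were 94% and 60%. For week 3, run on 16476 genes, they were 94% and 20%, and with 3 NLGF libraries, run on 16903 genes, 90% and 8%. With no change simulated, 0 of 34 gene lists were called, and a lysosome list shifted 1.2-fold was recovered. Genes were simulated independently of each other, so this does not show how the list test behaves where members are correlated. The shares recovered also hold no structure shared between genes. Changed genes, 50 at each fold, were drawn only from genes with a mean of at least 1 CPM. Recovery may therefore be lower in the real data, above all where few genes change.

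Alternatives were RLE scaling, the Wald test of DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in at least 10 samples, each library left out in turn and a block for sex and replicate number. For the genotype at each age they were also all 60 samples in 1 fit, no sex term, each sex alone, voom with sample quality weights, a test against a fold of 1.2, 1 or 2 surrogate variables from sva 3.50.0, and a covariate from the choroid plexus, ependyma, blood and neighbouring-region markers. Added after the data were seen were fits with and without 7 deeply sequenced week 3 libraries, a term for them, a fit without 1 library whose sex label conflicts with its counts, and a covariate for Lars2. Each count of calls was set against 100 splits of the samples, the real one included.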

Results

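Gene counts were obtained for the hippocampus of WT and NLGF mice at weeks 3, 8 and 24, with 5 samples labelled female and 5 labelled male in each of the 6 sets of 10. Total counts per library lay between 17.8 and 73.4 M with a median of 26.1 M. The WT libraries held 17.8 to 31.8 M counts at week 3, 19.3 to 28 M at week 8 and 21.3 to 33.8 M at week 24. The NLGF libraries held 20.2 to 35.2 M counts at week 8 and 24.4 to 29.9 M at week 24. The NLGF libraries of week 3 fell into 2 kinds. In 7 of them (females 1, 4 and 5 and males 2 to 5) totals were 54 to 73.4 M, while the 3 others (females 2 and 3 and male 1) lay with the WT libraries of that age, all 13 between 17.8 and 34 M.

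The 7 deeper libraries differed in content as well. Bc1, a short noncoding RNA of neurons (chromosome 7, 144914470 to 144914623), stood at 1780 to 5810 CPM in these 7 libraries and at 2.25 to 59.6 CPM in the other 53. No WT library is of this kind, so the genotype effect at week 3 could be compared within 1 library kind only between the 3 other NLGF libraries and the 10 WT libraries.

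**Figure D1:**
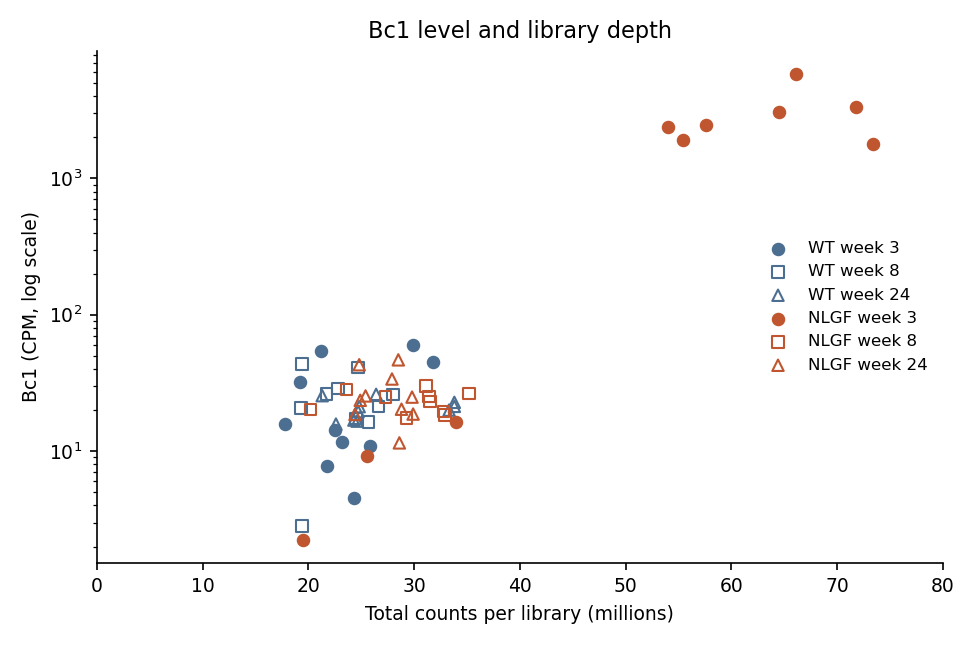
Bc1 level in CPM (log scale) against total counts in M, 1 point per library, by genotype and age. The 7 NLGF libraries of week 3 with over 50 M counts lie between 1780 and 5810 CPM, and all 53 others lie at or below 59.6 CPM.

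The sex label matched Xist and 4 genes of the Y chromosome in 59 libraries. The library labelled NLGF W3 male 2 did not match: it had 250 CPM of Xist and 0 CPM of Ddx3y, against at most 1.8 CPM of Xist and at least 38.7 CPM of Ddx3y in the other libraries labelled male. It stayed in the fits under its label. The library labelled NLGF W8 female 1 has a title of week 8 and an age field of 3 weeks, and it was kept with week 8.

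App, the gene that carries the knock-in mutations (chromosome 16, 84952666 to 85175255), had slightly lower counts in NLGF at each age. Its level was 1620 ± 109 CPM in NLGF and 1710 ± 86.1 CPM in WT at week 3, 1640 ± 76.4 and 1890 ± 233 CPM at week 8, and 1620 ± 101 and 1740 ± 61.1 CPM at week 24 (SD, n = 10 each). The log2 fold change of NLGF over WT was -0.09 ± 0.0498 (SE, adjusted p = 0.286), -0.21 ± 0.0619 (adjusted p = 0.633) and -0.10 ± 0.0383 (adjusted p = 0.375) in edgeR, so App was not called at any age with all libraries. At week 3 App was called with the 7 deeper NLGF libraries alone (-0.14 ± 0.0488, adjusted p = 0.0463), and it was at 0.000469 ± 0.0767 with the 3 others (adjusted p = 0.999). The difference of the App effect between ages was -0.01 ± 0.0681 for week 24 over week 3 (adjusted p = 0.977), -0.12 ± 0.0681 for week 8 over week 3 (adjusted p = 0.781) and 0.11 ± 0.0681 for week 24 over week 8 (adjusted p = 1).

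**Figure D2:**
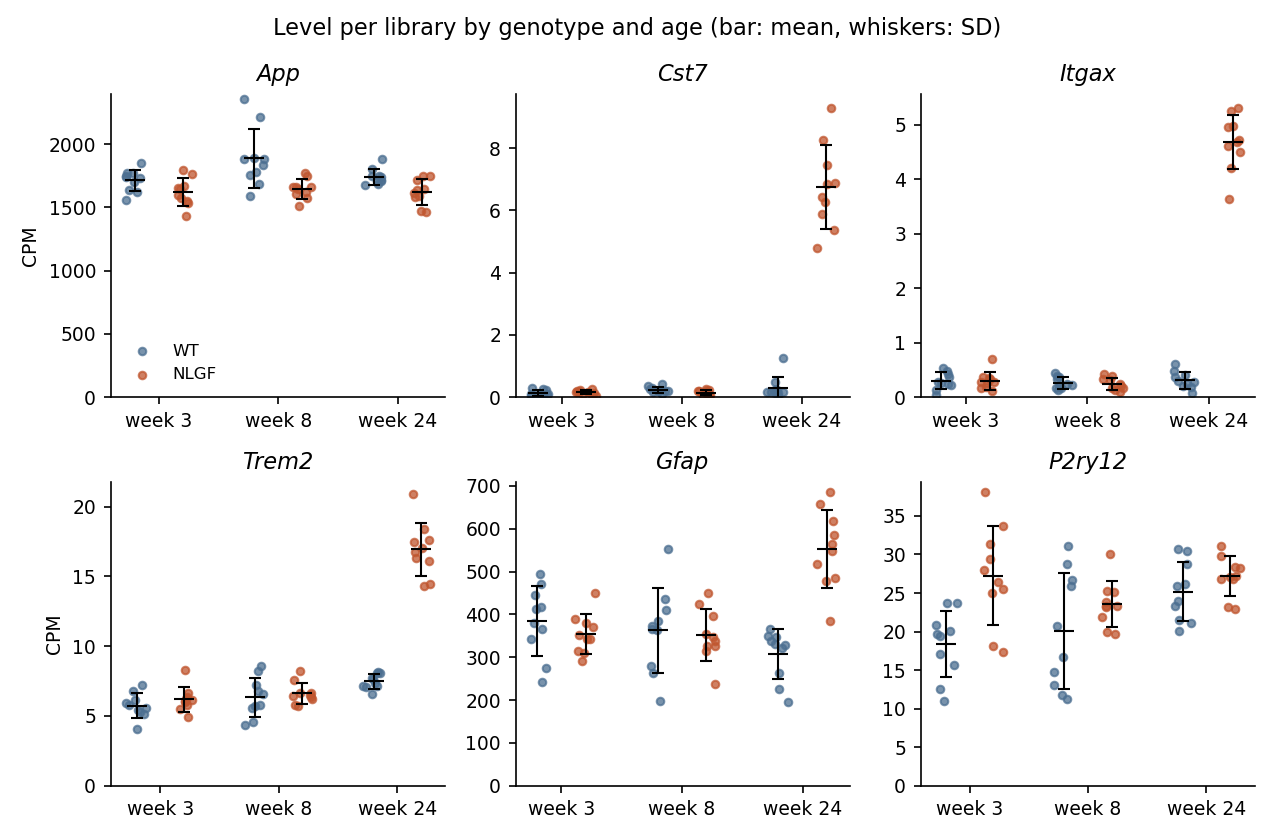
Level in CPM of 6 genes per library at weeks 3, 8 and 24, WT in blue and NLGF in red, with the mean as a bar and the SD as whiskers (n = 10 per set). Cst7, Itgax, Trem2 and Gfap are higher in all 10 NLGF libraries than in any WT library at week 24, P2ry12 is above all WT libraries in 1 of 10, and App lies between 1430 and 2350 CPM in every set.

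The comparison at week 3 asks whether the knock-in changes hippocampal expression in juvenile animals. Genes called included members of the cholesterol synthesis (11), nuclear oxidative phosphorylation (10), cytosolic ribosome (8) and mitochondrially encoded (6) lists, which are a small part of the 628, and no list was called with an estimated correlation. The calls of single genes depended on the 7 deeper NLGF libraries. Of 16605 genes tested, edgeR called 278 higher and 350 lower in NLGF, with 3649 at an unadjusted p under 0.05. Without the 7 deeper libraries the count was 0 (1965 at an unadjusted p under 0.05), and with a term for the deeper libraries it was also 0 (1885).

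The largest increases were Bc1 (log2 fold change 6.52 ± 1.19, adjusted p = 0.0151), Rny3 (4.39 ± 0.691, adjusted p = 0.015), Rny1 (3.62 ± 0.673, adjusted p = 0.0151), LOC108167575 (1.62), Snord64 (1.53), Adnp (1.49), Nptxr (1.49), ND2 (1.32), Hist1h2ae (1.15) and Cebpb (1.11). The largest decreases were Hist2h2aa1 (-1.07), LOC102640133 (-1.03), Srp54a (-0.94), Ifit3 (-0.90), Pin4 (-0.80), Ifit3b (-0.79), Timm8a1 (-0.78), Cox7c (-0.76), Gmnn (-0.76) and Sumo2 (-0.75). Histone, Ifit3 and Srp54a genes have close relatives in the genome, so their counts are uncertain. The smallest p-values belonged to Cox7c (adjusted p = 0.00099), Maml2 (0.51, adjusted p = 0.00653) and Aamdc (-0.45, adjusted p = 0.00772). In the 3 other NLGF libraries against all WT libraries, Bc1 was at -1.81 ± 0.582, ND2 at -0.39 ± 0.207, Adnp at 0.04 ± 0.334 and Gpr34 at 0.00 ± 0.182, whereas Cox7c was at -0.76 ± 0.165 and Maml2 at 0.55 ± 0.103 (adjusted p = 0.179 and 0.134). P2ry12 (0.58) and Gpr34 (0.66), both of the homeostatic microglia list, were called at week 3 and were at 0.73 and 0.85 in the deeper libraries, and P2ry12 was at 0.07 in the 3 others. Of 54 named genes, 48 had the same direction in the 3 others and 17 an unadjusted p under 0.05 as well, but the genes were named from a fit that holds these libraries and the WT libraries are shared. With separate WT libraries, 28.3 to 49.8% of the genes called with the deeper libraries had the same sign in the 3 others, over 10 ways to divide the WT libraries. Of the 55 named at week 3, 30 lost their call when some single library was left out.

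**Figure D3:**
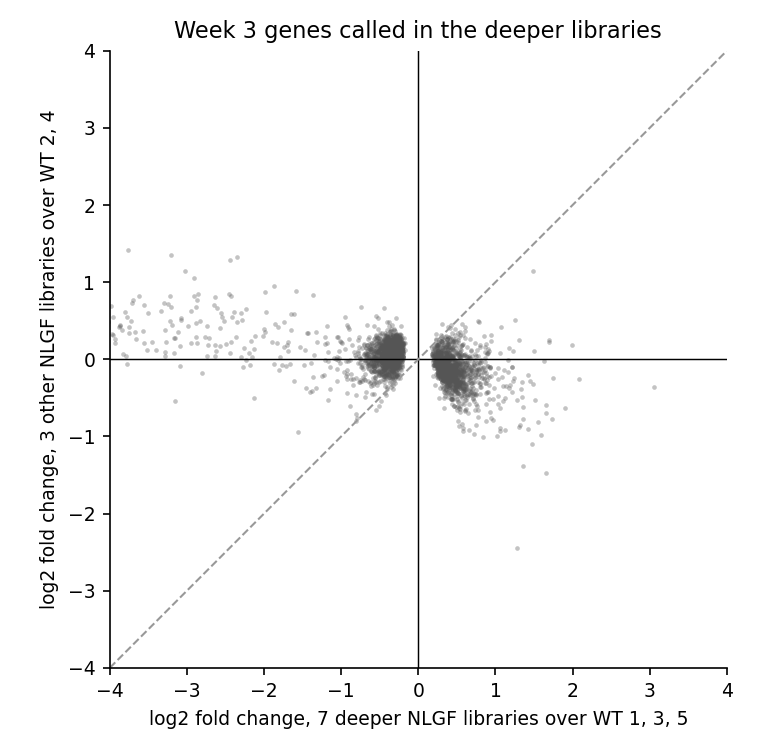
Log2 fold change of genes called between the 7 deeper NLGF libraries and WT libraries 1, 3 and 5 of each sex (horizontal) against that between the 3 other NLGF libraries and WT libraries 2 and 4 (vertical), 1 point per gene. Of 2860 genes, 26 lie outside the axes, and the points do not follow the dashed line of equal change, in the division of the WT libraries that gave the lowest share of 10.

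Among the gene lists at week 3, camera called cholesterol synthesis (median -0.25, 11 of 24 members called lower over all genes and 16 adjusted over the list alone, adjusted p = 1.23e-09), nuclear oxidative phosphorylation (-0.14, 10 of 28 and 14, adjusted p = 7.81e-08), cytosolic ribosome (-0.10, 8 of 30 and 13, adjusted p = 0.00043), antigen presentation (-0.24, adjusted p = 0.0343) and interferon response (-0.18, adjusted p = 0.0479) lower. Dentate gyrus granule cell (0.19, adjusted p = 0.0479) and synaptic vesicle and postsynaptic density (0.12, adjusted p = 0.0379) were called higher. None of the 7 was called with an estimated correlation: the cholesterol list had adjusted p = 0.214 with an estimated correlation, and fry called cholesterol synthesis (adjusted p = 0.000678) and oxidative phosphorylation (adjusted p = 0.00783). Of 13 mitochondrially encoded genes 6 were called higher, with a camera adjusted p of 0.823, because other members were lower (median 0.65, mean 0.15). The choroid plexus list had a median of 1.08 with 0 members called (camera adjusted p = 0.823).

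The count at week 3 moved by over 1.5 times when any of 15 single libraries was left out. It rose to 1923 without NLGF W3 male 1 and to 1381 without NLGF W3 female 2, which are libraries of the smaller kind. It fell to 250, 122 and 102 without NLGF W3 females 1, 4 and 5, and to 257, 191, 198 and 276 without the libraries labelled NLGF W3 males 2, 3, 4 and 5. It was 394, 193, 305 and 301 without WT W3 females 1, 2, 3 and 5, and 369 and 210 without WT W3 males 2 and 5.

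At week 8 the comparison asks whether expression differs in young adults. No single gene of microglia, astrocytes, neurons or App processing was set apart from the spread between samples. Of 16494 genes tested edgeR called 0, with 1292 at an unadjusted p under 0.05 and a smallest adjusted p of 0.633. voom called 0 and DESeq2 called 1, Ablim1, chosen after its value was seen (log2 fold change -0.16 in both tools, adjusted p = 0.0149 in DESeq2 and 0.633 in edgeR, 113 CPM in NLGF and 125 CPM in WT). Camera with the preset correlation called 8 lists, of which mitochondrially encoded genes (median 0.32, adjusted p = 2.11e-05), oligodendrocyte and myelin (0.20), replication-dependent histone (0.16), reactive astrocyte (0.13), dentate gyrus granule cell (0.12) and cytosolic ribosome (0.05) were higher and endoplasmic reticulum stress (-0.10) and synaptic vesicle and postsynaptic density (-0.06) lower. With an estimated correlation, and with fry, 0 lists were called, and the mitochondrial list had adjusted p = 0.839 with an estimated correlation. Adjusted over the list alone, 2 members of nuclear oxidative phosphorylation and 1 of cytosolic ribosome were higher and 2 chromatin regulators lower.

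At week 24 the question is which genes differ in the older NLGF animals. Genes of the plaque-associated microglia list rose most, up to over 20-fold, and with them rose genes of complement, antigen presentation, interferon response, lysosome and reactive astrocytes. Several genes of homeostatic microglia rose as well, by less, and P2ry12 and Tmem119 were not called. No shift of a neuronal list held with an estimated correlation, and the App-processing list was not called. Of 16508 genes tested edgeR called 132 higher and 13 lower, with 1484 at an unadjusted p under 0.05.

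Cst7 (chromosome 2, 150570415 to 150578944) stood at 6.75 ± 1.34 CPM in NLGF and 0.302 ± 0.356 CPM in WT (SD, n = 10 each), a log2 fold change of 4.51 ± 0.334 (SE, adjusted p = 3.17e-08). Itgax (chromosome 7, 128129526 to 128150657) stood at 4.68 ± 0.497 and 0.313 ± 0.156 CPM (3.89 ± 0.195, adjusted p = 4.68e-11). Clec7a stood at 3.68 ± 0.951 and 0.352 ± 0.219 CPM (3.37 ± 0.266, adjusted p = 3.98e-08). Trem2 (chromosome 17, 48346401 to 48352276) stood at 16.9 CPM (14.3 to 20.9) and 7.49 CPM (6.58 to 8.12) (1.18 ± 0.0656, adjusted p = 1.82e-10), and its partner Tyrobp at 18.5 ± 1.76 and 8.28 ± 0.988 CPM (1.16 ± 0.0701, adjusted p = 5.88e-10). The other genes with the largest increases were Ccl6 (2.31), Cd52 (1.62), Lyz2 (1.49), Gpr84 (1.35) and Siglecf (1.15). Gfap, the intermediate filament of astrocytes, stood at 553 ± 90.5 and 307 ± 58.2 CPM (0.86 ± 0.11, adjusted p = 5.67e-05). In each of Cst7, Itgax, Clec7a, Ccl6, Trem2, Tyrobp, Lyz2, Cd52 and Gfap, 10 of 10 NLGF libraries lay above all WT libraries.

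Of the 132 higher genes, 52 belong to one of the lists and 80 to none, and 25 rose at least 2-fold. The plaque-associated microglia list had 16 of 28 members called over all genes and 20 adjusted over the list alone (median 0.58, camera adjusted p = 9.54e-53). The counts were 11 of 20 and 13 for homeostatic microglia (0.34, adjusted p = 8.86e-24), among them Siglech (0.66), Olfml3 (0.53) and Cx3cr1 (0.36). They were 6 of 16 and 8 for complement (0.47, adjusted p = 2.92e-19), with C3ar1 (1.13), Itgb2 (0.75), C1qc (0.68) and C1qb (0.64). Antigen presentation had 3 of 18 and 13 (0.47, adjusted p = 3.89e-18), with Nlrc5 (0.90), Ctss (0.73) and B2m (0.65). Interferon response had 4 of 22 and 11 (0.42, adjusted p = 9.95e-18), with Trim30a (0.54), Xaf1 (0.53) and Irf9 (0.45). Lysosome had 7 of 28 and 8 (0.12, adjusted p = 5.62e-13), with Ctsd (0.57), Laptm5 (0.51), Gusb (0.46) and Grn (0.36). Reactive astrocyte had 4 of 21 and 7 (0.21, adjusted p = 2.07e-10), with Cd14 (0.94), Gfap (0.86), Gbp2 (0.65) and Osmr (0.54). These 7 lists were called with an estimated correlation too (adjusted p from 5.55e-06 to 0.0407) and with fry.

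With the preset correlation alone, camera called 7 more lists higher: ependyma (median 0.47), dentate gyrus granule cell (0.29), choroid plexus (0.23), replication-dependent histone (0.15), mitochondrially encoded (0.11), cholesterol synthesis (0.07) and cytosolic ribosome (0.04). It called 6 lower: immediate early (-0.28), circadian clock and glucocorticoid (-0.12), endothelium (-0.07), interneuron (-0.06), synaptic vesicle and postsynaptic density (-0.06) and nuclear oxidative phosphorylation (-0.04). None of these 13 held: the immediate early list had adjusted p = 0.353 with an estimated correlation and the ependyma list 0.423. The remaining 14 lists were not called, with medians from -0.17 to 0.11: astrocyte, oligodendrocyte and myelin, oligodendrocyte precursor, excitatory neuron, CA field pyramidal cell, immature neuron and proliferation, mural cell and meningeal fibroblast, blood, neighbouring brain regions, amyloid precursor processing and risk genes, App locus neighbours, endoplasmic reticulum stress, heat shock and chromatin regulators. In the immature neuron and proliferation list Mki67 was called (0.57 ± 0.12, adjusted p = 0.0157), and the median of that list was -0.01 against a mean of 0.06.

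**Figure D4:**
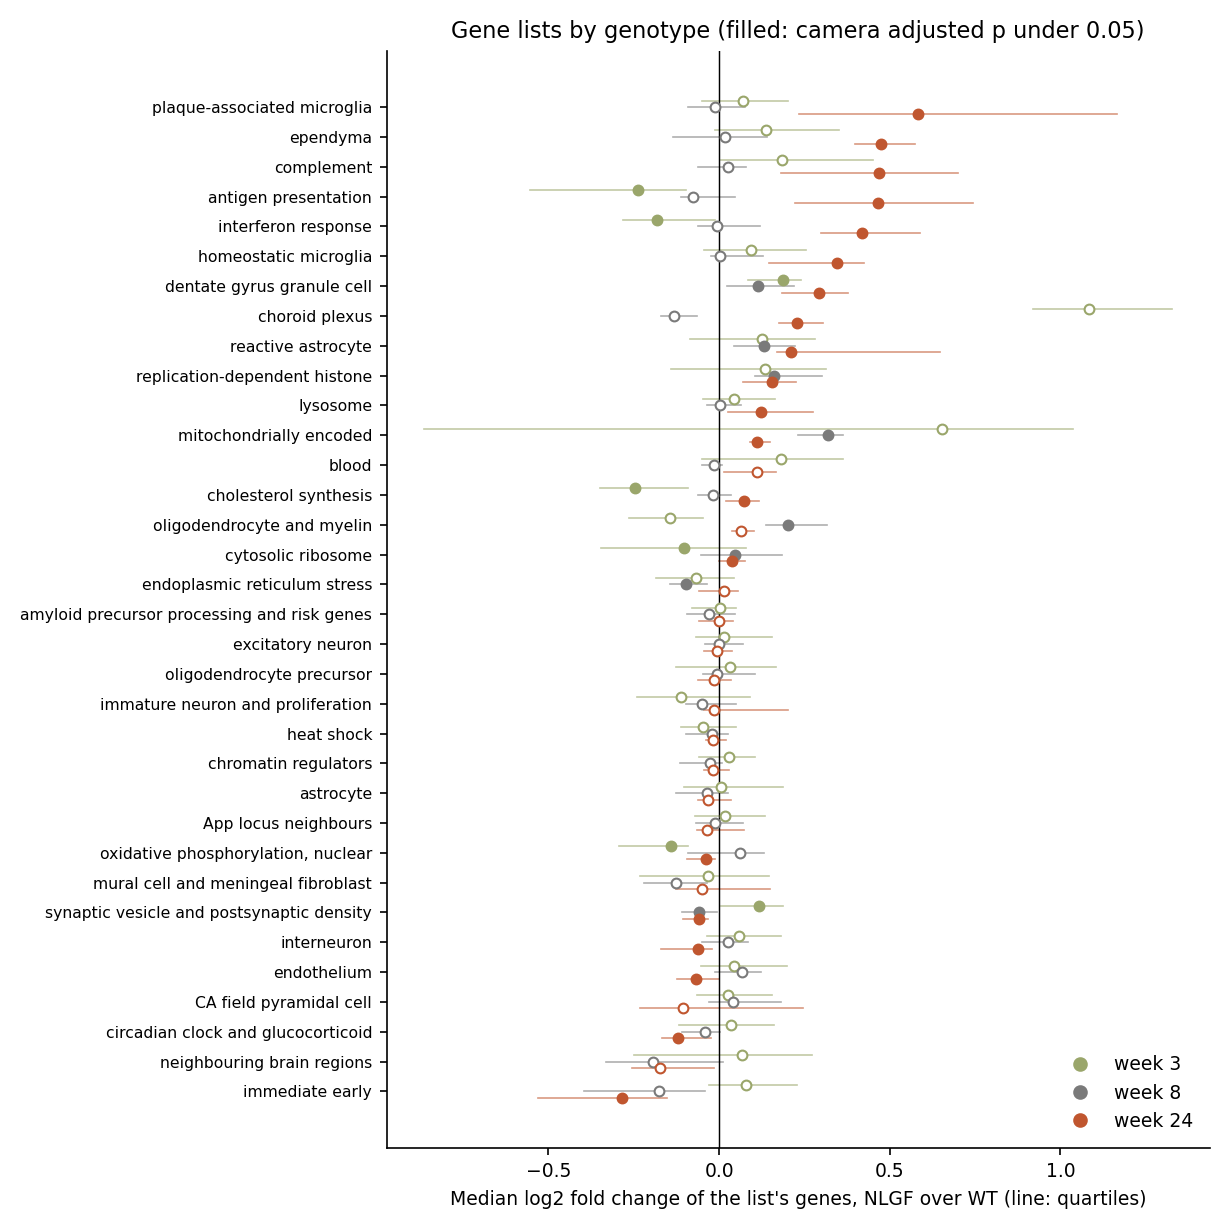
Median log2 fold change of NLGF over WT for each gene list (line: quartiles) at weeks 3, 8 and 24, filled where the preset camera test had an adjusted p under 0.05. At week 24 the plaque-associated microglia list has the highest median (0.58), and at week 8 it lies at -0.01.

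The largest decreases at week 24 were Mir6236 (-3.88 ± 0.889, adjusted p = 0.0457) and Lars2 (-3.18 ± 0.645, adjusted p = 0.0183), followed by LOC108167575 (-0.57), Ankrd63 (-0.43), Kirrel2 (-0.40), Rhbdl3 (-0.36), Ptpru (-0.30), Lsm8 (-0.29), Trp53rka (-0.27) and Cadps2 (-0.27). Lars2 stood at 59 ± 77.9 CPM in NLGF and 417 ± 242 CPM in WT, and its SD was over the mean in 5 of the 6 sets of libraries. With each library left out in turn the count of 145 stayed between 115 and 168, but Mir6236 lost its call in 16 of 20 such fits (adjusted p up to 0.113), Kirrel2 in 13, Trp53rka in 12, LOC108167575 in 8 and Lars2 in 4. Among the higher genes named, Xaf1 lost it in 15 of 20, Irf9 in 9, Osmr in 8, Gbp2 in 7 and Trim30a in 6.

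The difference of the genotype effect between ages was tested to ask when the effect appears. Single microglial genes such as Itgax and Tyrobp had a larger effect at week 24 than at either earlier age; no gene list was tested on the difference. Of the plaque-associated microglia list 12 members were among the genes higher than at week 8 and 13 among those higher than at week 3. Between weeks 24 and 8, 55 genes had a higher effect at week 24 and 0 a lower one (684 at an unadjusted p under 0.05, of 17752 tested), led by Mpeg1 (1.11 ± 0.0979, adjusted p = 5.56e-12), Cst7 (5.24), Itgax (3.99 ± 0.4), Tyrobp (1.12 ± 0.116) and Ccl6 (2.32 ± 0.248). Between weeks 24 and 3 the counts were 160 higher and 44 lower (2397), led by Mpeg1 (1.13 ± 0.0975, adjusted p = 2.68e-12), Tyrobp (1.18), Itgax (3.89), Ctss (0.98) and Ccl6 (2.38) and, lower, LOC108167575 (-2.18), Bc1 (-6.13), Gm38469 (-2.36), Rny1 (-3.97) and Adnp (-1.62). Without the 7 deeper libraries 15 genes were called, all of them among the 160, and the 5 named higher genes were kept. Between weeks 8 and 3, 27 genes were higher and 5 lower (1289), led by Rps3a1 (0.56), 2200002J24Rik (3.79), Gm10012 (1.73), Rpl37a (0.42) and Cox7c (0.74) and, lower, by Bc1 (-6.54), Rny3 (-4.27), Tshz1 (-0.57), Rny1 (-3.40) and Prdm1 (-1.07). Of these, Rny1 lost its call in 49 of 60 fits with a library left out, Prdm1 in 46, Tshz1 in 15 and Rny3 in 8. Without the 7 deeper libraries edgeR called 0 genes for weeks 8 and 3. The 204 calls for weeks 24 and 3 became 351, 366, 124 and 133 without NLGF W3 females 2, 3, 4 and 5, and 538 and 133 without NLGF W3 males 1 and 5. The 32 calls for weeks 8 and 3 became 8, 127, 115, 13 and 9 without NLGF W3 females 1 to 5 and 168, 11, 11, 19 and 20 without the libraries labelled NLGF W3 males 1 to 5. They became 21, 18, 16 and 16 without WT W3 females 1 and 3 and males 4 and 5, 20, 18, 20 and 16 without NLGF W8 females 4 and 5 and males 2 and 3, and 21 and 17 without WT W8 females 3 and 4.

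The genotype effect was compared between the sexes at each age. edgeR called 0 genes at weeks 3, 8 and 24, with 2012, 1046 and 534 at an unadjusted p under 0.05. DESeq2 called 81 at week 3 and 0 at the other ages. The week 3 fits hold the library labelled NLGF W3 male 2, whose sex label conflicts with its counts. The 81 can therefore not be read as effects that differ between the sexes. Without that library edgeR again called 0 genes, and DESeq2 was not run. In simulated data 56% of 2-fold and 20% of 1.5-fold differences between the sexes were recovered for week 3 (17302 genes), 54% and 24% for week 8 (17217 genes) and 78% and 24% for week 24 (17242 genes), and 0% of the smallest differences simulated at each age. Leaving out NLGF W3 male 1 gave 4 calls at week 3, and leaving out any other single library gave 0.

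Change with age in WT gives the scale of normal maturation. From week 3 to week 8, markers of oligodendrocyte precursors, dividing cells and immature neurons, cholesterol synthesis and blood fell. Myelin genes fell as well, although their list did not hold with an estimated correlation. Of 16844 genes tested 443 were higher and 759 lower, with 3386 at an unadjusted p under 0.05. Il33 (1.61 ± 0.151, adjusted p = 1.52e-08) and Hsf4 (1.17 ± 0.15, adjusted p = 2.07e-06) rose, as did Hmgn5 (1.40), Adnp (1.38), Nptxr (1.27), Ntn5 (1.15), LOC108167575 (1.09), Tchh (1.09) and Cebpb (1.05). Casr (-2.73 ± 0.239), Slc4a1 (-2.66), Eln (-2.07), Hbb-bt (-1.98), Il12rb1 (-1.97), Rab7b (-1.90), Slc45a3 (-1.83), Cldn14 (-1.78), Rnf122 (-1.64) and Gsn (-1.63) fell. Among the list genes Gpr17 (-1.37 ± 0.104, adjusted p = 3.16e-10), Mal (-1.45), Mag (-1.38), Cnp (-1.23), Top2a (-1.12), Mki67 (-0.98), Cyp51 (-0.72), Hmgcs1 (-0.70) and Dnmt3a (-0.77) were lower. The ages may have been processed apart, and the labels do not tell.

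Of the lists, oligodendrocyte and myelin had 16 of 22 members lower over all genes and 19 adjusted over the list alone (median -1.09, adjusted p = 2.84e-25), cholesterol synthesis 18 of 24 and 23 (-0.45, adjusted p = 5.52e-30), immature neuron and proliferation 10 of 23 and 13 (-0.46, adjusted p = 7.68e-14), oligodendrocyte precursor 9 of 16 and 11 (-0.41, adjusted p = 1.35e-10) and blood 6 of 6 and 6 (-1.56, adjusted p = 7.68e-14). Camera called 15 lists with the preset correlation and 4 of these with an estimated one: oligodendrocyte precursor, immature neuron and proliferation, blood and cholesterol synthesis. The myelin list had adjusted p = 0.0562 with an estimated correlation and was called by fry (adjusted p = 5.49e-05). The genes called in WT were followed in NLGF. Against the 3 other NLGF libraries of week 3, 95% of the higher and 96% of the lower genes moved the same way. Against the 7 deeper ones the shares were 82.5% and 94.1%, and there Adnp (-0.10), Nptxr (0.07), Cebpb (0.14), ND6 (-0.22) and LOC108167575 (-0.32) did not show the rise seen in WT.

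**Figure D5:**
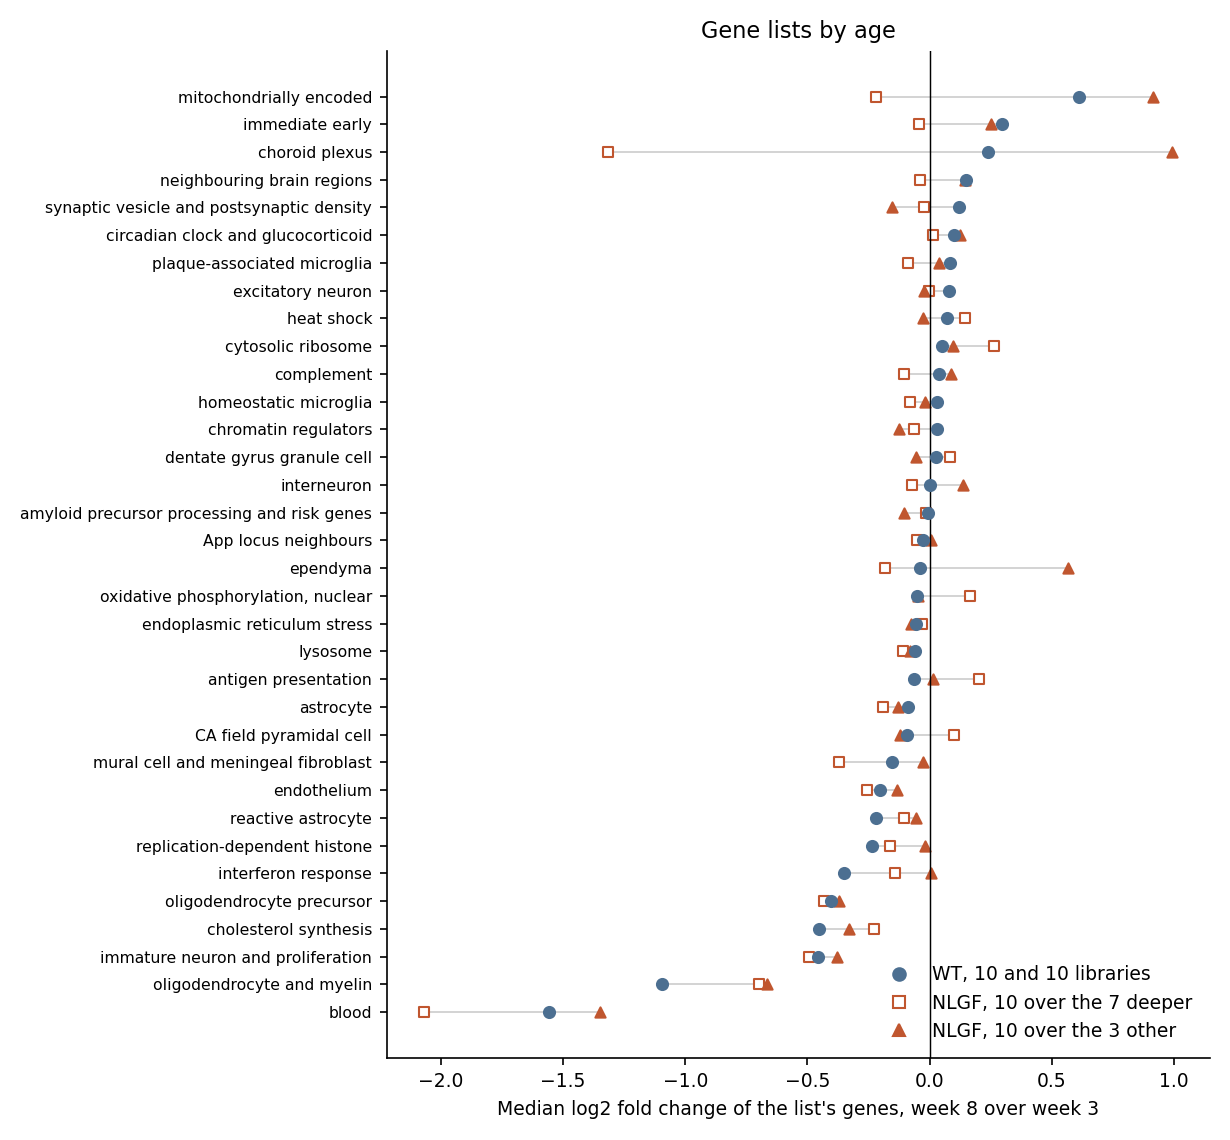
Median log2 fold change of week 8 over week 3 for each gene list in WT (circles), in NLGF against its 7 deeper week 3 libraries (squares) and in NLGF against the 3 others (triangles). Blood, myelin, precursor, proliferation and cholesterol lists are below 0 in all of these, and the mitochondrially encoded list is at 0.61 in WT and below 0 against the deeper libraries.

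From week 8 to week 24 markers of immature neurons and dividing cells fell further in WT, with 6 genes higher and 41 lower (1935 at an unadjusted p under 0.05). Top2a (-1.07 ± 0.162, adjusted p = 0.00297), Draxin (-1.31), Igfbpl1 (-1.62), Mki67 (-0.85), Gpr17 (-0.64) and Col3a1 (-1.73) fell, and Spag6 (0.98), LOC108167575 (0.79), Mlph (0.79), Zc3hav1 (0.54), Pcdhb14 (0.38) and Lin52 (0.31) rose. With a library left out, Lin52 lost its call in 14 of 30 fits, Mlph in 12, Pcdhb14 in 5 and Col3a1 in 3. The immature neuron and proliferation list had 9 of 23 members lower over all genes and 13 adjusted over the list alone (median -0.44), and it was the 1 list of 11 called by camera that held with an estimated correlation (adjusted p = 8.35e-05). The count of 47 became 29 and 28 without WT W24 males 1 and 2, and 31 and 81 without WT W8 females 2 and 3. The count of 1202 from week 3 to week 8 became 2029 without WT W8 female 1.

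The authors' deposited table lists 2628 genes at week 3, 4 at week 8 and 156 at week 24. The authors' deposited table gives an adjusted p above 0.05 for 241, 2 and 7 of these, up to about 0.06. Of the calls made here, 620 of 628 at week 3 and 125 of 145 at week 24 are in the authors' deposited table with the same direction. The 4 genes of week 8 in the authors' deposited table are App, Cpsf7, Fam193a and Tnfaip1, none of which was called here. Both sets of calls rest on the same samples and are not independent.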

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

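The fits by library depth, the fit without the library labelled NLGF W3 male 2, the Lars2 covariate, the interval of the median of short transcripts and the scatter of homeostatic markers were chosen only after the results were seen.

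Single libraries stood apart in 4 of 66 groups of 10 values tested for an isolated highest or lowest library, where chance marks about 1 in 20. Cst7 was 1.26 CPM in WT W24 male 3 (0.0442 to 0.485 CPM in the other 9) and Clec7a was 0.894 CPM in the same library (0.0404 to 0.413 CPM). Itgax was 0.703 CPM in NLGF W3 female 2 (0.121 to 0.367 CPM), and Trem2 was 8.28 CPM in NLGF W3 male 1 (4.89 to 6.65 CPM). The genotype effect differed between ages, by a test of the difference, in 204 genes for week 24 over week 3, in 32 for week 8 over week 3 and in 55 for week 24 over week 8.

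By the bound set beforehand, under 5 of 100 splits with as many calls, chance was argued against for 204 and for 55, and not for 32. As many genes were called by 1 of 100 splits for week 24 over week 3 (highest other 4), by 2 of 100 for week 24 over week 8 (highest other 720) and by 5 of 100 for week 8 over week 3 (highest other 763). The splits with 720 and 763 calls point to a structure of the samples beyond genotype, so the bound is weak for 55. The 204 became 15 without the 7 deeper NLGF libraries of week 3 and 26 with a term for them. That count cannot be read as an effect of genotype and age alone.

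The 628 genotype calls at week 3 were weighed first. Read depth alone was argued against, since thinning every library to the shallowest left 0.901 of the count (551 to 590 calls in 5 draws). Recovery of short transcripts stays open: the Spearman correlation of transcript length and fold change across genes was 0.146, between its bounds, and 0.398 among called genes (median length 4393.5 nt for those higher and 2049.5 nt for those lower), while 58 transcripts under 300 nt had a median log2 fold change of -0.073 (95% interval -0.216 to 0.183) with 5 called higher and 3 lower. A library batch of the 7 deeper NLGF libraries fits: genes called between them and some of the WT libraries had, in the 3 other NLGF libraries against the remaining WT libraries, a median signed change of -0.255 of the first, the lowest of 10 ways to divide the WT libraries (highest -0.003, median -0.128; 28.3 to 49.8% of genes with the same sign). Chance as such was argued against, since 2 of 100 splits gave as many calls, but the other of these 2, with 1894 calls, was the split that put all 7 deeper libraries on one side. An effect of genotype alone would have carried the changes over to the 3 other NLGF libraries. All 10 shares lay at -0.003 or below, which argues against genotype as the cause of these changes as a whole. The 10 divisions reuse the same WT libraries and rest on the same 3 other NLGF libraries. They are therefore not 10 independent tests, and the range of shares does not measure the spread between samples. For a single gene, batch and genotype cannot be told apart. An effect of genotype below what 3 libraries can show stays open.

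The rise of microglial genes at week 24 was weighed second. Chance was argued against, since 1 of 100 splits, the real one, gave 145 calls and the highest other gave 1. A larger share of microglia with no change per cell would raise alike all markers that microglia alone make. The test fixed beforehand, the median of the homeostatic list as a share of that of the plaque-associated list, was 0.592 (95% interval 0.255 to 0.896, 2-sided permutation p = 0.0271 for the difference of the medians), between its bounds. The interval and the p-value come from resampling the genes of the lists, so they do not measure the spread between samples. The 20 homeostatic markers lay apart by more than their errors, with a squared scatter of 5.98 in units of their squared SE (at most 2.22 under 99 sets of permuted labels). For example, P2ry12 was at 0.11 ± 0.0817 and Siglech at 0.66 ± 0.0858, so the markers did not rise by an equal amount. Markers also made by other cells would rise by less, and the permuted labels hold no rise. The scatter therefore cannot decide on a larger share of microglia as the whole cause. A larger share along with a change per cell stays open as well. Blood or meningeal cells in the tissue stay open by the bounds of 0.1 and 0.3 set beforehand. The medians were 0.11 (6 of 13 blood genes measured) and -0.051 (19 mural and meningeal genes). Both lie under the 0.3 that this explanation asks for, and 0 members of either list were called. But the higher median lies above 0.1, and 6 blood genes cannot speak for all blood cells. A response of microglia to the knock-in is likewise open.

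The lower App count in NLGF was weighed last. Loss of reads over the altered App exons, which may not map to mm10, stays open: it needs an equal effect at each age, and no difference between ages was called (smallest adjusted p 0.781), but week 8 over week 3 was at -0.118 ± 0.0681, which does not show equality. The counts are per gene, and the reads over those exons were not examined. Lower transcription of the knock-in allele would look the same and was not tested. At week 3 the fold change was 0.000469 in the 3 other NLGF libraries, with an SE of 0.0767.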

How the results depend on the processing

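The fits by library depth, the fit without the library labelled NLGF W3 male 2 and the Lars2 covariate were chosen only after the data were seen; all other settings were written before the data were examined. RLE scaling left every count of calls within 1.5 times its value, and all of the genes named at weeks 3 and 24 kept their call under it. Except where stated, the cause was not tested.

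The 628 calls at week 3 became 1486 with DESeq2, 351 with no filter, 1904 with all 60 samples in 1 fit, 3130 with voom and quality weights, 1752 with 2 surrogate variables, and 2 against a fold of 1.2. They became 6 in males and 190 in females, where fewer samples enter. The fit in males holds the library labelled NLGF W3 male 2, whose sex label conflicts with its counts. The deeper NLGF libraries are also unequally divided between the sexes. The 6 and 190 therefore do not show a difference between the sexes. They became 0 without the 7 deeper NLGF libraries and 0 with a term for them, 3671 without the 3 others, and 257 without the library labelled NLGF W3 male 2. The split of the 628 was 278 higher and 350 lower, and with RLE it was 309 and 336. The 0 calls of genotype by sex at week 3 became 81 with DESeq2, in a fit that holds the library with the conflicting sex label. The 0 genotype calls at week 8 became 1 with DESeq2. The 145 calls at week 24 became 224 with DESeq2 (all 145 shared), 58 against a fold of 1.2, 37 in males, 44 in females and 60 with Lars2 as a covariate (54 shared). Lars2 itself was called lower in NLGF at week 24 (log2 fold change -3.18), so this covariate can take up part of the genotype effect. The fall to 60 therefore does not show that the other calls are technical.

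For differences between ages, 204 (week 24 over week 3) became 308 with DESeq2, 124 with no filter, 15 without the deeper libraries and 26 with a term for them. The 32 (week 8 over week 3) became 80 with DESeq2, 21 with no filter, 0 without the deeper libraries, 0 with a term for them and 11 without the library labelled NLGF W3 male 2. The 55 stayed between 47 and 71. The 47 age calls of week 24 over week 8 became 111 with DESeq2.

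The labels do not say whether the replicate numbers pair the samples. Correlations of same-numbered samples lay between -0.292 and 0.426 over 10 comparisons of 5 pairs each, in which some libraries recur. By chance, 1 in 5 samples would correlate best with its own number. Samples did so in 14 of 50 cases. At week 24 these were 3 of 5 males and 3 of 5 females, with mean correlations of 0.122 and 0.153 (-0.031 and -0.039 with other numbers), so pairing at that age is not ruled out. With the replicate block the counts became 165 at week 3, 122 for week 8 over week 3 and 29 for age from week 8 to week 24, and no other count moved by over 1.5 times.

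Gene lists called by camera with the preset correlation numbered 7, 8 and 20 at weeks 3, 8 and 24, and 15 and 11 for age. With an estimated correlation they numbered 0, 0, 7, 4 and 1, and with fry 2, 0, 7, 7 and 1. At week 3 the preset correlation called 6 lists without the 7 deeper NLGF libraries, 4 of them among the 7, and 3 lists without the 3 others, all among the 7. An estimated correlation was not run on these 2 fits. At week 24 the preset correlation called 16 lists with Lars2 as a covariate, all 16 among the 20.

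Without the 7 deeper libraries the direction changed at week 3 for App (0.000469), Bc1 (-1.81), ND2 (-0.385), ND5 (-0.245), ND4 (-0.135) and COX1 (-0.254), and with a term for them for Bc1 (-1.62), ND2 (-0.324), ND5 (-0.208), ND4 (-0.0708) and COX1 (-0.234). The difference for Bc1 changed direction under these settings to 2.19 and 1.99 for week 24 over week 3 and to 1.78 and 1.58 for week 8 over week 3.

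With each library left out in turn, counts ran from 102 to 1923 at week 3, stayed 0 at week 8, ran from 115 to 168 at week 24, 124 to 538 for week 24 over week 3, 8 to 168 for week 8 over week 3, 49 to 64 for week 24 over week 8, 0 to 4 for genotype by sex at week 3 (0 at weeks 8 and 24), 999 to 2029 for age to week 8 and 28 to 81 for age to week 24. The number of libraries limits small effects: with 3 NLGF libraries at week 3, simulated on 16903 genes, 48% of 1.5-fold changes were recovered. Thinning every week 3 library to the shallowest left 0.901 of the calls, so depth limited that count little.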

Other observations

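No test in this part was fixed before the data were seen, except the splits of the samples.

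The library labelled NLGF W3 male 2 was the closest of 1770 pairs of libraries to NLGF W3 female 1, with a robust SD of the log2 ratio over 12341 genes of 0.111 against 0.274 at the median pair. Both had high Ttr (9340 and 9760 CPM) and no Ddx3y, and Bc1 at 1900 and 3330 CPM. Their counts differed by 5.46 times the counting noise, against 3.59 at the lowest of all pairs. This ratio can grow with depth and both libraries are of the deeper kind, so it does not show them to be less alike than that pair. Whether they come from 1 animal was not tested, and they were kept as separate samples.

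Lars2 and Mir6236 varied together within each of the 6 sets of 10 libraries (Spearman correlation 0.903 to 0.985), and so did Lars2 and Gm15564 (0.818 to 0.952) and LOC108167755 (0.745 to 0.976). Gm15564 shares 28 of its 816 25-base words with Lars2, so reads of these 2 can be shared, while Mir6236 shares 0 of its 99 words. LOC108167755 was not examined in this way. Lars2 ranged from 16.1 to 840 CPM over all libraries.

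WT W24 male 3 was the highest of the 10 WT libraries for 7 of the 25 genes that rose at least 2-fold at week 24, and its median position between the mean of the other WT libraries (0) and of NLGF (1) was 0.075.

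Genotype fold changes over 17752 genes were compared between ages, which share no samples. The Spearman correlation was 0.423 for weeks 3 and 8 (2-sided permutation p = 0.019) and 0.327 for weeks 8 and 24 (p = 0.047), over 1000 permutations of the labels. For weeks 3 and 24 it was 0.21, within the range of permuted labels (-0.215 to 0.211, 2-sided permutation p = 0.058). These are correlations across genes, which are not independent replicates, and the 95% range under permutation was as wide as -0.375 to 0.399. The week 3 fold changes include the deeper NLGF libraries, and no WT library is of that kind. Correlations with week 3 were not computed without those libraries. The values for week 3 therefore cannot show that an effect of genotype at that age recurs later. Of calls, 2 higher genes were shared by weeks 3 and 24 (2.07 expected of independent lists) and 2 lower (0.259 expected).

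Among the other splits of the samples, 0 calls are matched by all 100 splits, so nothing can be said of chance there, and the highest other split gave 1683 calls at week 8, 4, 60 and 1139 for genotype by sex at weeks 3, 8 and 24. Splits with over 1000 calls where the real one gave 0 point to a structure of the samples that the labels do not give. For age in WT, 1 of 100 splits gave 1202 calls for week 8 over week 3 (highest other 208). For week 24 over week 8, 1 of 100 gave 47 (highest other 0). Chance was argued against for both.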
